A study of Mus musculus with 24 samples.

How the data were processed

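RNA of tibia and femur from female mice was measured on 24 Affymetrix Mouse Gene 2.1 ST arrays, which carry probe sets along the whole length of each transcript. Wild-type mice and mice carrying an osteoblast-targeted transgene for 11-beta hydroxysteroid dehydrogenase type 2 were sampled at 3, 6, 12 and 18 months, with 3 arrays in each of the 8 groups. The labels' protocols state that marrow was flushed from the tibia. The labels do not say that each array is from a separate animal, so the p-values measure the spread between these samples, which may be technical in part.

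The deposited table holds 1 column of log2 values per array, and its log base was inferred from its values, which run from 0.09 to 13.7. MAS5 is the only tool named, per the submitters' processing notes, with no version. The background correction, summary and between-array scaling behind the deposited log2 values are not given in the sources used here. The median over all rows lay between 3.55 and 3.64 on all 24 arrays. The number of arrays limits the precision, and no detection call was used.

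Of 41034 rows, 23521 carried 1 gene symbol, 1814 carried several and 15699 were unnamed in the platform annotation. Rows with several symbols or none were tested apart and not named. Through their Entrez identifiers, 23328 of the rows with 1 symbol were matched to a RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Where a symbol had more than 1 row, as for 1082 genes, the row with the highest mean over all arrays stood for the gene, which left 22180 genes.

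All designs, gene lists, naming rules and most alternatives were fixed before the data were examined. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 24 arrays, with a term for each of the 8 groups and a term for the prefix of the code in each sample's source name. The code has 3 prefixes, whose meaning the labels do not state and which are spread unevenly over the groups. The fit left 14 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over genes, and a gene was called at an adjusted p under 0.05. The comparisons were transgenic against wild type at each age and as the mean of the 4 within-age differences, 18 against 3 months in each genotype, the difference between these age differences, and any difference among the 4 ages in each genotype by a moderated F-test. Comparisons of 6 with 3, 12 with 6 and 18 with 12 months over both genotypes were added after the data were seen.

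Shifts of 30 gene lists against all other genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the 30 lists of a comparison. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list's genes move one way on balance. List means per array, with no prefix term, were tested by exact permutation of genotype within age, over 160000 allocations. They were also tested by exact permutation of 18 against 3 months within genotype, over 400 allocations. Both permutation tests, and that of the glucocorticoid handling list without Hsd11b2, were added after the data were seen, and the smallest p they can give are 1.25e-05 and 0.005.

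Hsd11b2 was named in every comparison set beforehand except the F-tests. Otherwise the rule named the 10 largest rises and 10 largest falls among called genes, for the age comparisons those with every array of 1 group above every array of the other and for the genotype mean those with the same sign at all 4 ages. In the remaining comparisons it took up to 5 in each direction, or the 3 with the lowest p in each direction where fewer than 3 genes passed. From each list it took at most 4 called members, or 2 members that did not pass. Predicted genes, small RNA genes, receptor families and single immunoglobulin segments of the variable kind were counted and not named.

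The fit was tested on simulated data made from each gene's mean, fitted prefix effects and residual spread, with 50 genes changed at each size. Changes of 0.5, 1, 2 and 3 were placed in the same simulated arrays, with noise independent between genes. Many changed genes make the adjusted threshold easier to pass, so the shares below may be too high where few genes differ. For the genotype difference averaged over ages, 76% of genes changed by 0.5 on the log2 scale and 92% of those changed by 1 were recovered. For transgenic against wild type at 18 months the shares were 12% and 56%, and 92% at a change of 2. For 18 against 3 months in wild type they were 10%, 56% and 98%, and for the difference between the age differences 2%, 34% and 84%.

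Alternatives set beforehand were a fit with no prefix term, fits within a prefix, a replicate block, quantile normalization, median centring, leaving out genes below the 25th percentile of mean signal, testing every row, trended and robust variance, array weights, fits on only the groups compared, a fold minimum of 1.5, no variance shrinkage, and leaving out each array in turn. Added after the data were seen were the skeletal muscle list mean as a covariate, a fit without the 4 arrays whose muscle list mean lay below 7, and leaving out each array in turn for the means of called lists.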

Results

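The series holds log2 values of bone from wild-type and transgenic female mice at 3, 6, 12 and 18 months, on 12 arrays per genotype and 3 per group. The transgene directs 11-beta hydroxysteroid dehydrogenase type 2, the enzyme that inactivates glucocorticoids, to osteoblasts, the cells that build bone. The design asks how blocking glucocorticoid action in these cells alters bone transcripts, how these change with age, and whether age acts alike in both genotypes. Xist, which is transcribed from the inactive X chromosome, lay between 10.17 and 10.59 on all arrays. Correlations between arrays over genes ran from 0.96 to 0.991. The group mean of 16 skeletal muscle genes ran from 7.10 ± 1.71 (SD, n = 3) in wild type at 3 months to 10.01 ± 0.70 (SD, n = 3) in transgenic bone at 6 months. Within groups its SD ran from 0.25 in wild type at 6 months to 2.18 in wild type at 18 months.

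Averaged over the 4 ages, Hsd11b2, the gene the transgene carries, was 2.22-fold higher in transgenic than in wild-type bone, a log2 difference of 1.15 ± 0.12 (SE, limma adjusted p = 0.000211). Hsd11b2 measured 3.77 ± 0.20, 3.64 ± 0.04, 3.48 ± 0.17 and 3.60 ± 0.09 (SD, n = 3 each) in wild type at 3, 6, 12 and 18 months. In transgenic bone Hsd11b2 measured 5.25 ± 0.25, 4.54 ± 0.56, 4.48 ± 0.10 and 4.82 ± 0.32 (SD, n = 3 each) at the same ages. Within every age the lowest transgenic array lay above the highest wild-type array, most narrowly at 6 months (3.92 against 3.68). Hsd11b2 was the only gene called among 22180, while 1326 genes had an unadjusted p under 0.05, and 2 genes were called without wild-type 3-month replicate 3.

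**Figure D1:**
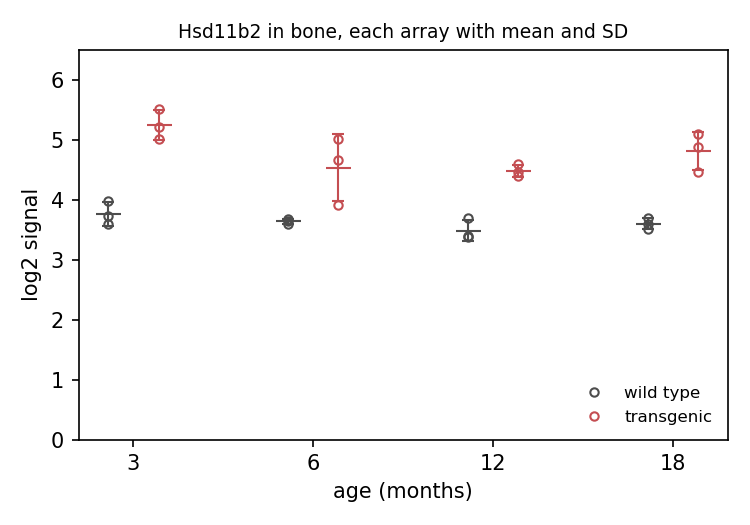
Hsd11b2 log2 signal (vertical axis) by age in months (horizontal axis) for wild-type and transgenic bone, with each array as a circle and the group mean and SD as a bar. The transgenic arrays lie between 3.92 and 5.52, the wild-type arrays between 3.38 and 3.98.

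No difference between genotypes was detected for the list of genes that glucocorticoids induce through their receptor. The arrays hold RNA of whole bone, so a change confined to osteoblasts, where the transgene is targeted, could go unseen. Of 20 measured response genes, 13 lay below 0 and none was called, over all genes or adjusted over the list alone, and the list mean differed by -0.06 (95% interval -0.21 to 0.08). Cebpd, a transcription factor, differed by 0.26 (adjusted p = 0.814), and Tgm2, a transglutaminase, by -0.22 (adjusted p = 0.814). The 15 neutrophil genes all lay above 0 in transgenic bone, with a median of 0.19 and Itgb2l, a neutrophil integrin, at 0.55 (adjusted p = 0.814). Camera called this list with its preset correlation (adjusted p = 7.44e-11), but adjusted p = 0.557 with an estimated correlation, and 1 member passed adjusted over the list alone. The 11 B cell genes all lay below 0, with a median of -0.24 and Cd79a, a part of the B cell receptor, at -0.38 (adjusted p = 0.863). The preset test called it at adjusted p = 0.00261, against adjusted p = 0.831 with an estimated correlation. Of 17 oxidative phosphorylation genes, 16 lay below 0 with a median of -0.12, for an adjusted p of 0.000172 with the preset and adjusted p = 0.831 with an estimated correlation.

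The preset test also called the chondrocyte list (median 0.35), collagen and matrix assembly (0.13), osteocyte (0.10) and osteoblast (0.16) as higher and cell cycle (-0.09) as lower. Each of these had adjusted p = 0.831 with an estimated correlation. Without the prefix term the list mean differences shrank from 0.163 to 0.021 for osteoblast, 0.121 to 0.024 for osteocyte, 0.157 to 0.079 for collagen, -0.085 to -0.050 for cell cycle and -0.105 to -0.020 for oxidative phosphorylation genes. The oxidative phosphorylation difference was -0.113 (95% interval -0.207 to -0.020) with the muscle list mean as a covariate and -0.142 (-0.271 to -0.013) without the 4 arrays lowest in muscle RNA, where the chondrocyte difference of 0.422 shrank to 0.223. Without transgenic 18-month replicate 1 the osteoblast, osteocyte and collagen differences were 0.054, 0.006 and 0.042, and in all 6 of the 9 called lists moved by over 1.5 times when some single array was left out. The glucocorticoid handling list, which holds Hsd11b2, was called too, with a median of 0.06 (adjusted p = 0.00261; adjusted p = 0.089 with an estimated correlation). The preset calls for this comparison numbered 9, and fry called 1 list, glucocorticoid handling (fry adjusted p = 0.000198). By exact permutation of genotype within age, the handling list alone differed (adjusted p = 0.000375), and its mean over the genes other than Hsd11b2 differed by 0.08 (exact permutation p = 0.0635). In the same permutation test the other lists did not pass, with neutrophil genes next at adjusted p = 0.239 and all other lists at adjusted p = 0.943. The remaining 21 lists had medians between -0.14 for erythroid and 0.11 for skeletal muscle genes.

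At single ages no gene was called by limma between genotypes. Genes with an unadjusted p under 0.05 numbered 872 at 3 months, 831 at 6 months, 1264 at 12 months and 972 at 18 months. Hsd11b2 differed by 1.48 ± 0.22 (SE) at 3 months, where its adjusted p was 0.0598, by 0.92 ± 0.23 at 6 months, by 0.99 ± 0.25 at 12 months and by 1.21 ± 0.22 at 18 months. The other genes with the lowest p included Rtl3 (1.16, adjusted p = 0.88) and Keg1 (-1.28, adjusted p = 0.88) at 3 months. At 12 months the chemokine gene Ccl9 differed by 1.06 (adjusted p = 0.711), and at 18 months Ube2dnl2 differed by -1.01 (adjusted p = 0.354). The 14 chondrocyte genes all lay above 0 at 3 months, with a median of 1.31 and a camera adjusted p of 9.75e-08, but adjusted p = 0.918 with an estimated correlation. Its list mean difference of 1.28 became 0.64 without transgenic 3-month replicate 1 and 2.09 without transgenic 3-month replicate 3, and that of muscle genes turned from 0.68 to -0.27 without wild-type 3-month replicate 1. The muscle (0.69), erythroid (-0.34) and cell cycle (-0.24) lists were called there too, each with adjusted p = 0.918 with an estimated correlation, as was the handling list (adjusted p = 0.436 with an estimated correlation). At 6 months the B cell (-0.59), neutrophil (0.23) and osteoblast (-0.37) lists were called, each with adjusted p = 0.984 with an estimated correlation, as was the handling list (adjusted p = 0.156 with an estimated correlation). Fry called the handling list alone at 3, 6 and 18 months (fry adjusted p = 0.0184, 0.0189 and 0.039). This list holds Hsd11b2. With no prefix term its mean differed by 0.365, 0.294 and 0.324 at these ages, and by 0.087, 0.144 and 0.102 without Hsd11b2. At 18 months the neutrophil median was 0.44 and the B cell median -0.83, called at adjusted p of 1.03e-12 and 4.26e-07, both with adjusted p = 0.295 with an estimated correlation. The neutrophil list mean differed by 0.44 (95% interval 0.07 to 0.80), by 0.62 (0.09 to 1.15) within the commonest code prefix and by 0.60 (0.20 to 1.00) without the 4 arrays lowest in muscle RNA. Both settings leave out wild-type 18-month replicate 1, whose neutrophil mean of 9.90 was the highest of the wild-type arrays at this age, so they are not separate checks. The prefix leaves 2 arrays per genotype at 18 months. The B cell list mean differed by -0.76 (-1.44 to -0.08), by -0.78 (-1.65 to 0.09) and -0.64 (-1.47 to 0.19) under these settings, and by -0.405 (-1.064 to 0.255) without transgenic 18-month replicate 3. The adipocyte (median -0.28, 19 of 20 genes below 0) and chondrocyte (0.68, all 14 above 0) lists were called there at adjusted p of 0.000265 and 0.000319, both with adjusted p = 0.915 with an estimated correlation. The adipocyte list mean differed by -0.44 (95% interval -1.20 to 0.32), by -1.18 (-1.98 to -0.38) within the commonest code prefix and by -0.94 (-1.76 to -0.12) without the 4 arrays. It was -0.94 and -0.15 without wild-type 18-month replicates 1 and 2, and -1.044, -0.165 and -0.266 without transgenic 18-month replicates 1, 2 and 3. The chondrocyte list mean differed by 0.86 (-0.66 to 2.38), by -0.02 without transgenic 18-month replicate 2 and by 1.65 without transgenic 18-month replicate 3. At 12 months, where all 3 wild-type arrays share a code prefix that only 1 transgenic array carries, the preset test called 12 lists, none of them with an estimated correlation (lowest adjusted p = 0.679). They were osteoblast (0.62), collagen (0.60), osteoclast (0.50), Wnt (0.46), osteocyte (0.39), marrow stromal (0.36), neutrophil (0.12), cell cycle (-0.27), oxidative phosphorylation (-0.36), erythroid (-0.40), tendon (-0.86) and skeletal muscle genes (-1.04). Without the prefix term the list mean of muscle genes turned from -1.06 to 0.41, and those of osteoblast (0.68), collagen (0.55), osteoclast (0.42), Wnt (0.39), marrow stromal (0.36), oxidative phosphorylation (-0.35), erythroid (-0.37) and tendon genes (-0.69) shrank to 0.28, 0.34, 0.08, 0.19, 0.175, -0.06, -0.21 and -0.15. Left-out single arrays moved the list mean by over 1.5 times for 4 of 5 called lists at 3 months, 3 of 4 at 6 months, 10 of 12 at 12 months and 3 of 4 at 18 months. Leaving out transgenic 3-month replicate 1 or wild-type 3-month replicate 2 gave 1 called gene at 3 months, as did no prefix term, array weights and the muscle covariate there, transgenic 6-month replicate 3 at 6 months, wild-type 12-month replicates 1 and 2 at 12 months and wild-type 18-month replicates 2 and 3 at 18 months.

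Between 3 and 18 months in wild-type bone, genes of matrix-forming bone cells were among those that fell and genes of fat cells among those that rose. Bglap, which encodes osteocalcin, fell from 6.80 to 4.32, a modelled difference of -2.72 ± 0.55 (SE, limma adjusted p = 0.0198, n = 3 per age). The fibrillar collagen genes Col11a1 (-2.91), Col5a2 (-2.71) and Col3a1 (-2.58) fell along with Lum (-2.67), a matrix proteoglycan gene. Plin1, which coats the lipid droplets of fat cells, rose by 3.12 ± 0.64 (SE, adjusted p = 0.0217), and Ighg3, an immunoglobulin heavy chain gene, rose by 3.61 ± 0.78 (SE, adjusted p = 0.0259). A dimmer row of Ighg3 differed by 2.33 and did not pass (limma adjusted p = 0.277). In all, 310 genes were higher and 282 lower at 18 months, and Hsd11b2 differed by -0.13 (adjusted p = 0.896).

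All 14 measured osteoblast genes lay lower at 18 months, with a median of -1.61. Of these, 7 were called over all genes and 14 adjusted over the list alone, among them Bglap, Omd (-2.27), the alkaline phosphatase gene Alpl (-1.67) and the parathyroid hormone receptor gene Pth1r (-1.61). Camera gave an adjusted p of 7.27e-16 with its preset and adjusted p = 0.174 with an estimated correlation. For this comparison fry called 7 of the 30 lists (lowest fry adjusted p = 0.0161), against 13 by camera's preset and 0 with an estimated correlation. The 19 collagen and matrix assembly genes also all lay lower, with a median of -1.50, 9 called over all genes and 18 adjusted over the list alone. Serpinh1, a collagen chaperone, fell by 1.71 and the fibronectin gene Fn1 fell by 1.48 (list adjusted p = 2.84e-17; adjusted p = 0.174 with an estimated correlation). Among 14 cartilage genes, with a median of -1.71, Col11a2 was called at -2.54, and 5 passed adjusted over the list alone (list adjusted p = 8.64e-06; adjusted p = 0.356 with an estimated correlation). The Wnt antagonist genes Wif1 (-1.89) and Sfrp4 (-1.23) fell within a list of 18 whose median was -0.63, where 3 passed adjusted over the list alone (list adjusted p = 0.000509; adjusted p = 0.378 with an estimated correlation). None of 14 osteoclast genes was called, over all genes or adjusted over the list alone, although all lay below 0 (median -0.27, list adjusted p = 0.0133; adjusted p = 0.454 with an estimated correlation).

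All 20 adipocyte genes lay higher at 18 months, with a median of 1.40, and 11 were called over all genes and 17 adjusted over the list alone. Scd1, a fatty acid desaturase, rose by 2.56 and Cd36, a fatty acid transporter, rose by 1.57, while the list had an adjusted p of 6.18e-20 with the preset and adjusted p = 0.174 with an estimated correlation. Slc2a4, the insulin-responsive glucose transporter that muscle also expresses, rose by 1.83. The skeletal muscle list mean stood at 7.10 ± 1.71 at 3 months and 9.35 ± 2.18 at 18 months (SD, n = 3 each). Its 16 genes had a median of 3.03, with none called over all genes and 16 adjusted over the list alone (list adjusted p = 4.77e-16; adjusted p = 0.192 with an estimated correlation). Of the 310 risers, 64.5% had a within-group correlation with the muscle list mean above 0.5, against 5.1% of all genes and 0.7% of the genes that fell. The called muscle-correlated genes included Rbm24 (3.04), Cacng1 (2.98) and Popdc3 (2.81). Of 17 oxidative phosphorylation genes, 4 were called, among them Cycs (0.71) and Idh3a (1.03), and 15 passed adjusted over the list alone (median 0.53, list adjusted p = 1.18e-13; adjusted p = 0.174 with an estimated correlation). Their correlations with the muscle list mean were 0.73 for Cycs and 0.75 for Idh3a.

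Plasma cell genes had a median of 1.23, with Jchain, which joins immunoglobulin polymers, called at 2.24, and 5 of 9 passing adjusted over the list alone (list adjusted p = 3.74e-05; adjusted p = 0.179 with an estimated correlation). The glucocorticoid response list had a median of 0.27, where Zbtb16, a zinc finger gene, rose by 1.41 and 3 of 20 passed adjusted over the list alone (list adjusted p = 0.00322; adjusted p = 0.27 with an estimated correlation). No gene of the macrophage, B cell, or T and NK cell lists was called, over all genes or adjusted over the list alone, with medians of 0.46, 0.67 and 0.50. Their list adjusted p values were 0.00196, 0.00822 and 0.0056, against adjusted p = 0.356, 0.413 and 0.29 with an estimated correlation. The remaining 17 lists were not called, with medians from -0.41 for osteocyte to 0.28 for marrow stromal cell genes. Called members of these lists included Ppargc1a (3.01), a coactivator of mitochondrial genes, Irs2 (0.75), Nampt (0.64), Atf3 (2.03) and Nr4a1 (1.81), and Ptprv fell by 0.99. Ppargc1a had a within-group correlation of 0.63 with the muscle list mean. Outside the lists, Gpnmb, a glycoprotein gene of osteoclasts and macrophages, rose by 3.03.

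The wild-type count fell to 247 without the prefix term, with 42 higher and 205 lower, to 3 with the muscle list mean as a covariate and to 300 (259 higher, 41 lower) without the 4 arrays lowest in muscle RNA, and was 603 (440 higher, 163 lower) with only the groups compared and 544 (413 higher, 131 lower) within the commonest code prefix. It was 99 (28 higher, 71 lower) with no variance shrinkage, 1002 (571 higher, 431 lower) with array weights and 860 (341 higher, 519 lower) with median centring. It fell to 1 without 3-month replicate 1, 82 without 3-month replicate 2, 160 without 18-month replicate 2 and 9 without 18-month replicate 3, and the list means of muscle (3.19), glucocorticoid response (0.31) and osteoclast genes (-0.38) became 2.12, 0.19 and -0.23 without 3-month replicate 1, 18-month replicate 2 and 18-month replicate 3.

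In transgenic bone, genes of matrix and mineralization were among those that fell over the same ages. Muscle genes and the immunoglobulin gene Ighg3 were among the risers. Slc13a5, a citrate transporter of mineralizing cells, fell by 2.98 ± 0.67 (SE, limma adjusted p = 0.0343, n = 3 per age), and Smpd3, a sphingomyelinase needed for mineralization, fell by 2.77 ± 0.56 (SE, adjusted p = 0.0256). Bglap fell by 2.51 and Ranbp3l fell by 2.61. Ighg3 rose by 3.52 and Gpnmb by 3.01 ± 0.45 (SE, adjusted p = 0.00813), as did Ppargc1a (3.18) and the muscle genes Xirp1 (3.55) and Asb12 (3.33). The dimmer row of Ighg3 differed by 1.64 and did not pass (limma adjusted p = 0.513). A dimmer row of Asb12 differed by -0.11 and did not pass either (limma adjusted p = 0.841). In all, 92 genes were higher and 268 lower at 18 months, and 50% of the risers had a within-group correlation above 0.5 with the muscle list mean, which was 7.78 ± 1.67 at 3 and 9.85 ± 0.80 at 18 months (SD, n = 3 each). Hsd11b2 differed by -0.40 (adjusted p = 0.502).

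Among the osteoblast genes, 8 of 14 were called over all genes and 14 adjusted over the list alone, with a median of -1.75, including Pth1r (-1.74) and Ifitm5 (-1.83), a gene of mineralizing osteoblasts. The list had an adjusted p of 5.92e-17 and adjusted p = 0.236 with an estimated correlation. For this comparison fry called 3 of the 30 lists (lowest fry adjusted p = 0.0229), against 13 by camera's preset and 0 with an estimated correlation. Collagen and matrix assembly had a median of -1.75, with 6 of 19 called and 19 adjusted over the list alone, among them Plod2 (-1.77), a collagen lysine hydroxylase (list adjusted p = 1.21e-18; adjusted p = 0.236 with an estimated correlation). Wif1 fell by 2.10 and Col11a2 fell by 2.32, in lists whose medians were -0.68 (adjusted p = 0.312 with an estimated correlation) and -2.00 (adjusted p = 0.293 with an estimated correlation). Adjusted over the list alone, 6 Wnt and 10 chondrocyte genes passed. Of the 20 adipocyte genes, all lay above 0 with a median of 1.02, and only Slc2a4 was called over all genes (1.54), with 14 adjusted over the list alone (list adjusted p = 1.41e-12; adjusted p = 0.236 with an estimated correlation). Plasma cell genes had a median of 1.24, with 4 of 9 adjusted over the list alone and none over all genes (list adjusted p = 4.25e-05; adjusted p = 0.236 with an estimated correlation). None of the 16 genes of the muscle list or the 17 of the oxidative phosphorylation list was called over all genes, with medians of 2.86 and 0.49, and 16 and 12 passed adjusted over the list alone (both adjusted p = 0.236 with an estimated correlation). Klf15, a glucocorticoid-induced transcription factor, rose by 1.55 in a response list with a median of 0.21 (list adjusted p = 0.00843; adjusted p = 0.312 with an estimated correlation). The megakaryocyte (0.60), neutrophil (0.20), macrophage (0.28) and osteoclast (-0.30) lists were called by the preset test, with adjusted p = 0.408, 0.645, 0.637 and 0.637 with an estimated correlation. The transgenic count was 97 (47 higher, 50 lower) within the commonest code prefix, 29 (29 higher, 0 lower) when only the 6 arrays compared entered the fit, 6 with the muscle covariate and 222 (35 higher, 187 lower) without the 4 arrays lowest in muscle RNA. It was 66 (10 higher, 56 lower) with no variance shrinkage, 640 (159 higher, 481 lower) with median centring and 553 (187 higher, 366 lower) with array weights. It was 0 without 18-month replicate 3, 4 without 3-month replicate 2 and 209 without 3-month replicate 1. Without 18-month replicate 3 the list means of osteoblast (-1.73), chondrocyte (-1.99), Wnt (-0.64), osteoclast (-0.365), megakaryocyte (0.56), glucocorticoid response (0.26) and neutrophil genes (0.22) became -1.12, -1.07, -0.26, -0.10, 0.23, 0.41 and 0.10. Chondrocyte genes also became -3.02 without 18-month replicate 2 and -1.26 without 3-month replicate 1, adipocyte genes (1.12) became 0.72 without 18-month replicate 1, and muscle genes (3.00) became 1.98 without 3-month replicate 1.

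**Figure D2:**
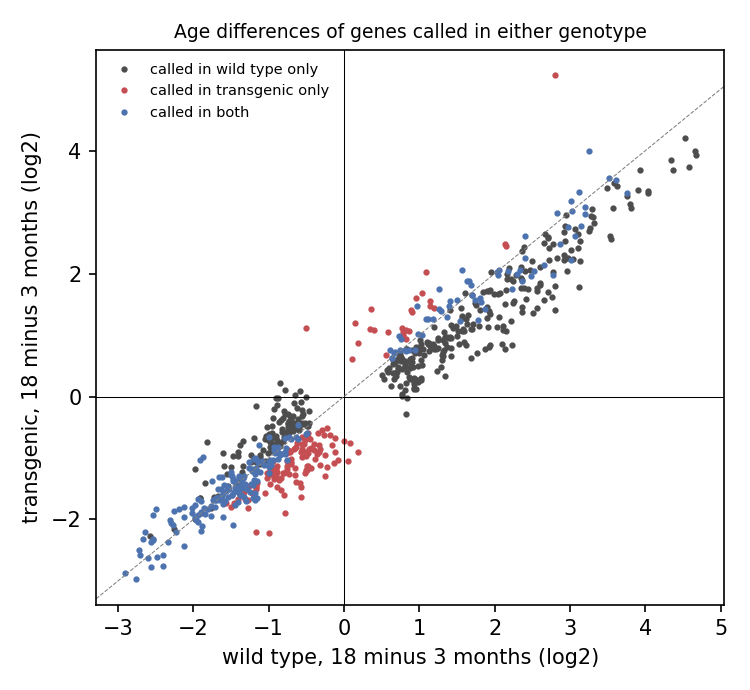
Log2 difference between 18 and 3 months in wild-type bone (horizontal axis) and in transgenic bone (vertical axis) for genes called in either genotype, coloured by where each was called, with a dashed line of equal differences. Of 592 genes called in wild type, 586 had the same sign in transgenic bone.

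The age differences of both genotypes pointed the same way for nearly all called genes. Of genes called in wild type, 586 of 592 had the same sign in transgenic bone, and of genes called in transgenic bone, 355 of 360 had the same sign in wild type. Both calls were shared by 65 risers, such as Ighg3, Gpnmb and Ppargc1a, where independent lists would share 1.29, and by 158 fallers, such as Bglap and Col5a2, against 3.41. The genotypes share no arrays in this comparison but share the prefix term and the spread estimate of the fit, and without the prefix term 12 risers and 133 fallers were shared, against 0.07 and 2.32. Muscle RNA, lowest on average at 3 months in both genotypes, could add to the shared rises, which was not tested. Of the risers, 64.5% in wild type and 50% in transgenic bone correlated above 0.5 with the muscle list mean, against 0.7% of the fallers in each. For the shared risers named here the correlations were 0.42 for Ighg3, -0.38 for Gpnmb and 0.63 for Ppargc1a. The expected counts also ignore correlation between genes.

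Limma detected no gene whose age difference differed between genotypes (0 called, 754 genes with an unadjusted p under 0.05). In the simulated data this comparison recovered 2% of genes changed by 0.5 and 34% of those changed by 1, so such differences could go unseen. Zfp119b, a zinc finger gene, had the lowest adjusted p at 0.713, with a difference of 1.62 ± 0.30 (SE), and Hsd11b2 differed by -0.27 ± 0.31 (SE, adjusted p = 1). The osteoblast list mean differed by -0.08 (95% interval -1.30 to 1.15), beside age changes of -1.65 in wild type and -1.73 in transgenic bone. The preset test called 4 lists, adipocyte and B cell as lower and neutrophil and cell cycle as higher, each with adjusted p = 0.916 with an estimated correlation.

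Over the 4 ages, the osteoblast list mean was highest at 3 months in both genotypes, and the plasma cell mean was highest at 18 months. The osteoblast list mean was 9.58 ± 0.24, 8.51 ± 0.59, 7.73 ± 0.38 and 7.96 ± 0.36 in wild type and 9.74 ± 0.24, 8.06 ± 0.74, 8.01 ± 0.31 and 8.05 ± 1.01 in transgenic bone (SD, n = 3 each, from 3 to 18 months). The plasma cell list mean was 6.24 ± 0.14, 6.62 ± 0.15, 7.20 ± 0.56 and 7.36 ± 0.06 in wild type and 6.44 ± 0.12, 6.70 ± 0.37, 7.32 ± 0.20 and 7.51 ± 0.51 in transgenic bone. A moderated F-test over the ages called 293 genes in wild type, among them Bglap (adjusted p = 0.0408), Cemip (adjusted p = 0.0168), which takes part in hyaluronan breakdown, and the muscle gene Mb (adjusted p = 0.0329). It called 399 in transgenic bone, among them Gpnmb (adjusted p = 0.0039) and Col10a1 (adjusted p = 0.0149), the collagen of hypertrophic cartilage. The wild-type count was 1, 7 and 191 without 3-month replicates 1, 2 and 3, 187 and 76 without 6-month replicates 2 and 3, 490 without 12-month replicate 2, 510 without 18-month replicate 1 and 46 without 18-month replicate 3. The transgenic count was 191, 15 and 131 without 3-month replicates 1, 2 and 3 and 242 without 12-month replicate 2. With only the groups compared the counts were 13 in wild type and 1 in transgenic bone, with no variance shrinkage 13 and 98, with the muscle covariate 3 and 19, without the 4 arrays lowest in muscle RNA 186 and 139, and with array weights 596 and 643. The wild-type count was 182 with no prefix term and 588 with median centring, and the transgenic count was 5 within the commonest code prefix. With both genotypes averaged, 555 genes were higher and 1039 lower at 6 than at 3 months. This count of 1594 became 789 (176 higher, 613 lower) without wild-type 6-month replicate 2 and 520 (71 higher, 449 lower) with the muscle covariate. It became 0 by limma, with 2105 genes at an unadjusted p under 0.05, among the 5 arrays of 1 code prefix, which leave 1 residual degree of freedom, and 1203 (530 higher, 673 lower) among the 13 arrays of the commonest prefix. Limma called 0 genes between 6 and 12 months and 0 between 12 and 18 months, where 1139 and 1216 genes had an unadjusted p under 0.05. With only the groups compared 1 gene was called between 6 and 12 months, and with median centring 1 between 12 and 18 months. Leaving out wild-type 12-month replicate 1 gave 6 and 1 genes, and leaving out wild-type 12-month replicate 3, transgenic 12-month replicate 3 or transgenic 18-month replicate 3 gave 1 between 12 and 18 months.

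**Figure D3:**
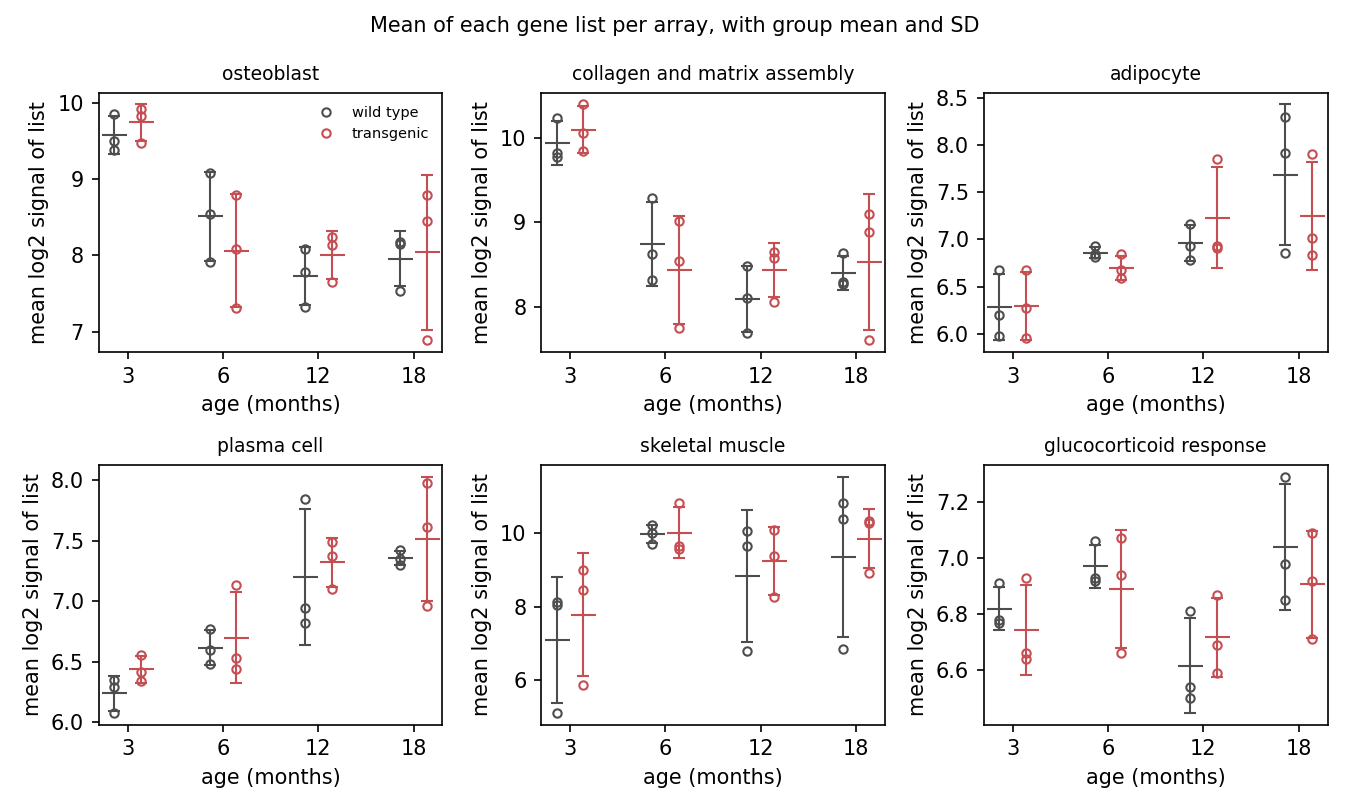
Mean log2 signal over the genes of 6 lists (vertical axes) by age in months (horizontal axes) for wild-type and transgenic bone, with each array as a circle and the group mean and SD as a bar. The osteoblast mean lies at 9.58 ± 0.24 in wild type at 3 months and 7.96 ± 0.36 at 18 months, and the muscle mean spreads from 5.12 to 10.81 over arrays.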

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

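The tests with the muscle covariate, of list means without single arrays, over other blood and vessel lists, of the prefix layout as the whole cause and of marrow and chance for the neutrophil and B cell lists were chosen only after the results were seen. The difference between the age changes of the genotypes drew attention for 4 lists by camera with its preset correlation: adipocyte (median -0.286), neutrophil (0.30), B cell (-0.872) and cell cycle (0.287). Each had adjusted p = 0.916 with an estimated correlation, and single left-out arrays moved each list mean by over 1.5 times, such as B cell from -0.887 to -0.532 without transgenic 18-month replicate 3. Among 17513 probe sets without a single gene symbol, which were tested apart from the genes, 4 were called between 18 and 3 months in wild type and 1 in transgenic bone.

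Adipocyte and oxidative phosphorylation genes were higher at 18 than at 3 months in wild type, where the muscle list mean was also higher on average. With the muscle list mean as a covariate, the oxidative phosphorylation difference was 0.227 (95% interval -0.016 to 0.471) in place of 0.526, and the adipocyte difference was 1.356 (0.290 to 2.421) in place of 1.576. The oxidative phosphorylation interval reaches below 0, so muscle RNA could account for part or all of that rise. The adipocyte interval leaves out 0, which argues against muscle RNA as the whole cause of the adipocyte rise. Muscle RNA could still account for part of it. Its share cannot be told apart from age here, since muscle group means are lowest at 3 months in both genotypes and the intervals are wide. The ages were compared directly, but age as the cause of either rise stays open.

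Osteoblast genes were lower at 18 than at 3 months in wild type, with a list mean difference of -1.653. Dilution by muscle RNA would lower other cell types alike, but the erythroid, neutrophil, endothelial and megakaryocyte lists together differed by 0.015 (95% interval -0.324 to 0.355), which argues against dilution as the whole cause. Among arrays of the commonest code prefix the osteoblast difference was -1.771, with an interval of -3.194 to -0.349 that leaves out 0, which argues against the layout of the prefixes as the whole cause. Its upper end missed the bound set beforehand, so a part of the difference could still come from the layout. With the muscle covariate the difference was -1.736 ± 0.572 (SE) against -1.653 ± 0.431 (SE). The ages were compared directly, but age as the cause of the fall stays open.

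Neutrophil genes were higher and B cell genes lower in transgenic bone, averaged over ages. Marrow left in the bones would raise the neutrophil (0.231, 95% interval 0.039 to 0.423), B cell (-0.255, -0.612 to 0.102), erythroid (-0.163, -0.524 to 0.198, 0 of 7 genes above 0) and megakaryocyte lists (0.021, -0.294 to 0.336) together; B cell and erythroid genes point against it, but their intervals reach above 0, so it stays open. The exact within-age permutation p of the neutrophil minus B cell mean was 0.0122. That p met the bound of 0.05 written before the test, and the reading of this test was changed after the p was seen. The bound was wrong because the pair was picked among 30 lists for its shifts, and over these lists the neutrophil list alone had a permutation adjusted p of 0.239, so chance and genotype cannot be told apart.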

How the results depend on the processing

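The settings with a muscle covariate and without the 4 arrays lowest in muscle RNA, and the list means without single arrays, were chosen only after the data were seen; the cause was not tested for any change given here. Hsd11b2, averaged over ages, passed under every setting run. Counts for 18 against 3 months in wild type (592) were 247 with no prefix term, 39 with a replicate block, 1002 with array weights, 99 with no variance shrinkage, 3 with the muscle covariate and 300 without the 4 arrays. In transgenic bone (360) they were 97 within the commonest prefix, 29 with the block, 640 with median centring, 553 with weights, 29 with only the groups compared, 66 with no shrinkage, 6 with the covariate and 222 without the 4 arrays. For any age difference in wild type (293) they were 182 with no prefix term, 26, 588, 596, 13 and 13 with block, centring, weights, only the groups compared and no shrinkage, 3 with the covariate and 186 without the 4 arrays. In transgenic bone (399) they were 5 within the prefix, 146, 643, 1 and 98 with block, weights, only the groups compared and no shrinkage, 19 with the covariate and 139 without the 4 arrays. Between genotypes at 3 months 1 gene was called with no prefix term, with weights and with the covariate. Leaving out 1 array gave 1 to 651 and 0 to 395 genes for 18 against 3 months in wild type and transgenic bone, 1 to 510 and 15 to 465 for any age, 1 to 2 for the genotype mean, 0 to 1 at each single age and 0 to 0 for the difference between age changes. Of 240 list tests, 64 were called with the preset, 0 with an estimated correlation and 14 with fry. Reversed medians were, with no prefix term, skeletal muscle at 12 months (0.388) and osteoblast for the genotype mean (-0.015) and, with the block, osteoblast at 6 months (0.071) and erythroid (0.079) and marrow stromal genes (-0.004) at 12 months. Single left-out arrays moved the list mean by over 1.5 times for 6 of 9 called lists of the genotype mean, 3 of 13 and 9 of 13 for 18 against 3 months in wild type and transgenic bone and 4 of 4 for the difference between age changes. Replicate numbers were not taken to pair the arrays, since 8 of 12 same-number pairs, not all, correlated above 0.1 (-0.30 to 0.29). After the prefix term 0 did, and 7 correlated best with their own number before it. Most same-number pairs share a code prefix, so the prefix term removes variation they share and this check cannot exclude pairing. The check set genotypes against each other within an age, while the block for the age comparisons joined replicate numbers across ages. A pseudocount was not run on log2 values, nor the genotype mean within a prefix.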

Other observations

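The permutation of list means over age, the counts of genes over other splits and the relation of the first component to muscle were tests chosen only after the results were seen. By exact permutation of 18 against 3 months within genotype, whose smallest possible p is 0.005, T and NK cell genes differed by 0.47 and macrophage genes by 0.43 over both genotypes (permutation adjusted p = 0.025 and 0.0375). Osteoblast (-1.66), collagen and matrix assembly (-1.56), adipocyte (1.17) and plasma cell genes (1.10) and the glucocorticoid handling list (0.20) had the same permutation adjusted p of 0.025, and the Wnt list (-0.64) had 0.0375, while for skeletal muscle genes (2.16) it was 0.104. The permuted means carried no prefix term, although the code prefixes other than the commonest differ between the 3-month and 18-month arrays. By camera none of the lists that passed this permutation was called with an estimated correlation, from adjusted p = 0.174 to adjusted p = 0.378 with an estimated correlation in wild type and from adjusted p = 0.236 to adjusted p = 0.637 in transgenic bone. The preset test did not call the handling list (adjusted p = 0.151 in wild type and 0.194 in transgenic bone) or T and NK cell genes in transgenic bone (adjusted p = 0.0662). On the first principal component, which held 25.2% of the variance, all 3-month arrays lay at 32.55 or above and all others at 10.04 or below. The muscle list mean moved with this component, at a correlation of -0.78 over the 24 arrays, -0.90, -0.72 and -0.81 within the 3 code prefixes (n = 13, 6 and 5) and -0.67 over the 18 arrays of 6 months and older.

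The arrays were also split in other ways, and each count of splits below includes the real split. The genotype mean's 1 called gene was matched or passed in 10 of 100 splits, 9 of them other than the real one (highest other 35). This count alone does not exclude chance, although Hsd11b2 itself had an exact permutation p of 1.25e-05, the smallest possible. The 9 lists called for the genotype mean were matched in 54 of 100 splits (highest other 17), so chance is not excluded. For the difference between age changes limma called 0 genes, with 754 at an unadjusted p under 0.05. Any split reaches 0, so this count cannot test chance (highest other 1). Counts as high as the real one for any age difference came in 2 of 100 splits in wild type (293 genes, highest other 361). In transgenic bone the real split alone reached its count (399 genes, 1 of 100, highest other 328). Both shares lie under 0.05, unadjusted over comparisons, so chance is less likely but not excluded. With 3 arrays against 3, the 10 splits are too few for a share under 0.05. Between genotypes, limma called 0 genes at each single age, with 872, 831, 1264 and 972 at an unadjusted p under 0.05 at 3, 6, 12 and 18 months. Any split reaches 0, so these counts cannot test chance (highest others 2, 5, 4 and 3). Comparing 18 with 3 months gave 592 genes in wild type, reached by the real split alone (1 of 10, highest other 1). The same comparison gave 360 in transgenic bone, again reached by the real split alone (1 of 10, highest other 7). The 13 lists called for age in wild type were reached by the real split alone (1 of 10, highest other 12). In transgenic bone 3 of 10 splits reached 13 lists, the real one included (highest other 16).

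A hypothesis is that the Hsd11b2 signal of a transgenic array may follow its share of osteoblast RNA, as the transgene is targeted to these cells. Over the 9 transgenic arrays of 6 months and older, Hsd11b2 correlated with the osteoblast list mean at 0.71 (exact permutation p = 0.03, adjusted 0.09 over 3 relations; Spearman 0.62, exact permutation p = 0.0857). Without the pair of arrays farthest out the correlation was 0.65, and within the commonest code prefix it was 0.66 (n = 6, exact permutation p = 0.146). In wild type it was -0.07 (n = 9, exact permutation p = 0.868). The relation is consistent with the hypothesis before adjustment and does not pass after it.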
